A study of Capra hircus with 6 samples.

How the data were processed

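Small RNA was sequenced from the longissimus dorsi muscle, the long muscle of the back, of Haimen goats at 2 stages, with 3 libraries each: fetuses at day 75 of pregnancy and newborn animals, called lambs in the labels, at 1 day of age. Per the labels' protocols, 2.5 ng of RNA per sample entered a TruSeq small RNA library preparation, fragments of the wanted size were cut from a polyacrylamide gel, and libraries were sequenced on an Illumina HiSeq instrument. The aligner, the miRBase release, the number of reads a miRNA needed to be listed and the goat genome build are not given in the sources used here. The only genome build that the submitters' processing notes name is mm9, a mouse build, and no coordinates are reported for that reason.

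The deposited files used here give names and numbers of distinct miRNAs. Read counts and expression levels are not used here. The first is a list of names of all expressed miRNAs with 1 of 3 classes set by the authors against miRBase, the public miRNA registry. The second gives, per the file headers, the number of distinct mature miRNAs and of distinct precursor hairpins (pre-miRNAs) in each library and over the 6 libraries together, sorted by the authors into 6 annotation classes. The third gives the deposited number and percent of listed sequences at each length for all libraries together. Per the file's own criteria, class gp1a holds reads matched to the specific miRBase entries, with hairpins found in the genome and ESTs. Class gp1b holds matches to the other selected miRBase entries, with hairpins likewise found in the genome and ESTs. In class gp2a the hairpin was not found in the genome, but the read was, at a site able to fold into a hairpin. In class gp3 neither hairpin nor read was found in the genome. Class gp4 holds predicted miRNAs with no match to the selected miRBase hairpins. The criterion of class gp2b is not used, so what this class holds is not known here.

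Libraries were assigned to a stage by their titles. The numbers of distinct miRNAs were compared between stages by a two-sided exact permutation test of the difference of means. Its 20 assignments of 3 libraries against 3 allow no p below 0.10, so no such comparison can pass 0.05. P-values were adjusted by Benjamini-Hochberg within each family of 6 or 7 classes. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical. The depth of the libraries is unknown, and a miRNA missing from a library cannot be told from one below its detection limit. Differences are given as lamb minus fetus. From the 6-library totals and the best single library of a stage, the highest possible number of miRNAs confined to the other stage was computed.

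Each name was split into species prefix, miRNA, arm and variant suffix. In the suffixes, L and R give the bases gained or lost at the 5′ and 3′ end relative to the registry entry, and ss gives substitutions with their position. New arms have no registry entry, so for them the reference of such a suffix is not known here. This reading of the suffix is the usual notation and is not spelled out in the files, but every name classed as differing carried such a suffix and none classed as identical did. Positions are as printed in the names, taken to be counted from 1 at the 5′ end. Names occurring on several rows were counted once. The 16 miRNA lists (families, genomic clusters, tissue and cell type markers) were written before the data were examined, and a name belonged to a list when its miRNA matched without species, arm and suffix. The miRNAs of the striated muscle list are all named. The planned rule for other names, by size and significance of a change or by abundance, was not applied, because it needs levels. Names given from other lists are examples, and single names in the closing section were chosen after their values were seen.

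The RefSeq annotation of goat assembly ARS1.2 was used only for the names of its 264 miRNA genes and for which of them are neighbours. All 264 symbols could be read as miRNA names. Whether a list's genes had a listed product more often than the other annotated genes was tested by a two-sided Fisher's exact test for the 15 lists with at least 3 annotated genes, with Benjamini-Hochberg adjustment. Genes of a cluster are not independent, so these p-values describe the catalogue. Intervals on shares are exact (Clopper-Pearson) at 95%, and cover counting error only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The permutation test of substitutions (100000 permutations) was tested on simulated data: with the positions of the 204 observed combinations of family, substitution and position shuffled, the most widespread substitution, chosen anew each time, passed 0.05 in 2% of 100 simulations. With 10 families carrying G9T added, it passed in 95%. This is a stronger signal than the 9 families observed with G9T, so the 95% does not hold for a signal of the observed size.

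The planned tests of differing miRNAs, of lists moving between stages and of the share of the most abundant miRNAs need a level per library and were not run. Alternatives for the number of distinct miRNAs were the exclusion of predicted miRNAs and leaving out each library in turn. Pre-miRNAs, subsets of classes and pairs of same-numbered libraries were added after seeing the data, as were the alternatives for the shares of names and genes and for substitutions.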

Results

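Small RNA libraries from goat longissimus dorsi muscle were compared between the fetal stage at day 75 of pregnancy and newborn lambs at 1 day of age, with 3 libraries per stage. The question was how the miRNA profile of this muscle differs between mid-gestation and birth. Over the 6 libraries together, 1120 distinct mature miRNAs were reported, the same number as the distinct names listed. Sequence variants of 1 miRNA and entries of other species count separately among them. The hairpins of the 6 classes add up to 944, and whether a hairpin falls in several classes was not checked. The numbers per library describe which part of this catalogue was detected at each stage. The names of the miRNAs were listed for all libraries together, and the level of a named miRNA at either stage is not analysed here. The depth of the libraries is unknown.

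Fewer distinct miRNAs, with sequence variants counted separately, were detected in every lamb library than in any fetal library. The fetal libraries held 955, 901 and 864 miRNAs, and the lamb libraries held 800, 780 and 820. The means were 907 ± 45.8 (SD, n = 3) in fetuses and 800.0 ± 20 (SD, n = 3) in lambs, which is 11.8% lower in lambs. The difference, lamb minus fetus, was -107 miRNAs and exceeded the spread of either group. The two-sided exact permutation test gave p = 0.10, the smallest value that 3 against 3 libraries allow (adjusted p = 0.175 over 7 comparisons). Counted as hairpins, summed over the classes, the means were 748 ± 37.1 (SD, n = 3) in fetuses and 673 ± 18.4 (SD, n = 3) in lambs, again without overlap.

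The difference was unevenly spread over the annotation classes. Predicted miRNAs with no match to known hairpins (class gp4) showed the largest relative difference, with 102 ± 9.07 in fetuses and 65.0 ± 4 in lambs (SD, n = 3 each), 36.1% lower. Matches to the specific miRBase entries (class gp1a) numbered 380 ± 12.5 in fetuses and 345 ± 9.07 in lambs, 9.04% lower. Matches to other selected miRBase entries with hairpins in the genome (class gp1b) numbered 163 ± 15.5 and 140 ± 3.79, 14.3% lower. In these 3 classes the stages did not overlap (exact permutation p = 0.10 each, the smallest possible, adjusted p = 0.175). Counted as hairpins, gp1a and gp4 again did not overlap between stages, whereas gp1b did, with 122 ± 13.7 in fetuses and 106 ± 2.08 in lambs (SD, n = 3 each, exact permutation p = 0.30). A split without overlap arises by chance in 10% of comparisons of 3 against 3.

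**Figure D1:**
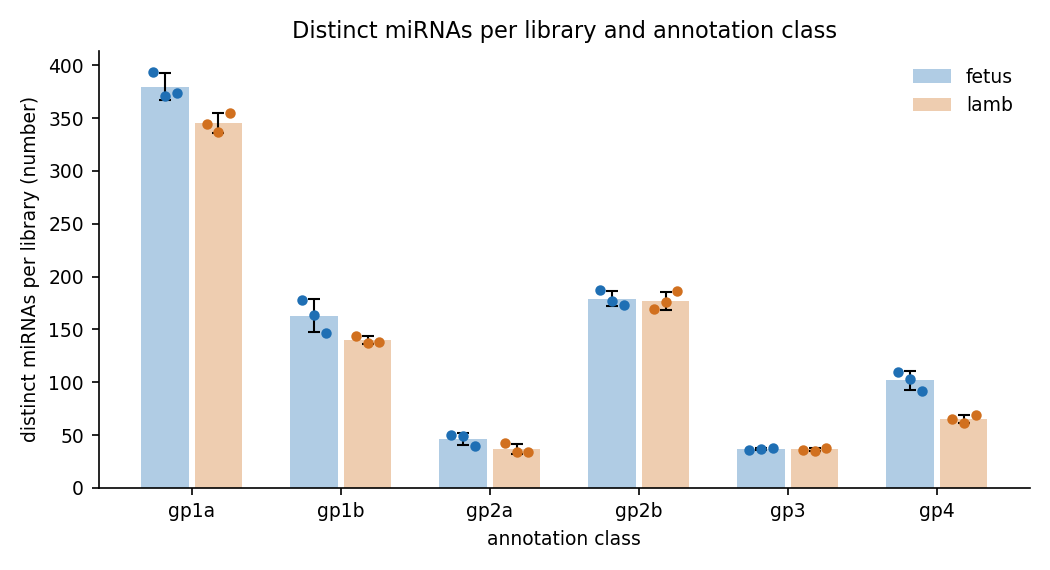
Number of distinct miRNAs per library (vertical axis) in each of 6 annotation classes (horizontal axis), for fetuses and lambs. Bars are means, error bars the SD of 3 libraries and points single libraries; the stages separate in gp1a, gp1b and gp4 and overlap in gp2a, gp2b and gp3.

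The numbers in the other classes overlapped between the stages. Class gp2a held 46.3 ± 5.51 miRNAs in fetuses and 36.7 ± 4.62 in lambs (SD, n = 3 each, exact permutation p = 0.20). Class gp2b held 179 ± 7.21 and 177 ± 8.54 (exact permutation p = 0.70). Class gp3, with neither hairpin nor read found in the genome, held 37.0 ± 1.00 and 36.3 ± 1.53 (exact permutation p = 0.80). As a share of each library's miRNAs, predicted miRNAs made up 11.2% ± 0.479 in fetuses and 8.12% ± 0.297 in lambs. Class gp2b made up 19.7% ± 0.239 in fetuses and 22.1% ± 0.867 in lambs (SD, n = 3 each). Class gp3 made up 4.09% ± 0.315 in fetuses and 4.54% ± 0.0814 in lambs (SD, n = 3 each). None of these 3 shares overlapped between stages (exact permutation p = 0.10 each, adjusted p = 0.20 over 6 shares). Counted as hairpins, the gp3 share overlapped, with 5.05% ± 0.400 in fetuses and 5.50% ± 0.154 in lambs (SD, n = 3 each, exact permutation p = 0.20), and the gp4 and gp2b shares did not.

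The catalogue limits how many miRNAs can have been confined to 1 stage. Of the 407 miRNAs of class gp1a, 394 were present in a single fetal library, so at most 13 (3.19%) were seen in lambs only. This limit rests on fetus replicate 1, without which it would be 33. At most 52 (12.8%) were seen in fetuses only, since 355 were present in a single lamb library. In class gp4 these limits were 58 of 168 (34.5%) for lambs only and 99 of 168 (58.9%) for fetuses only. Over all classes, at most 163 of 1120 miRNAs were lamb-only and at most 286 were fetus-only. These limits also rest on single libraries. Without fetus replicate 1 the lamb-only limit would be 215, and without lamb replicate 3 the fetus-only limit would be 313. A miRNA of class gp1a was found in 5.34 of 6 libraries on average, against 2.98 for a predicted miRNA.

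Of the 1120 distinct names, 293 (26.2%, 95% exact interval 23.6 to 28.8%) had a sequence identical with the miRBase entry and 534 (47.7%, 44.7 to 50.7%) differed from it. The remaining 293 were new: 168 predicted miRNAs, the same number as in class gp4, and 125 sequences from an arm of a known hairpin that has no registry entry. Goat entries gave 372 of the 952 names that were not predicted, and cattle entries gave 218. Of the goat-prefixed names, 57.8% were identical with their entry and 39.5% differed. Of the 580 names from entries of other species, 13.4% were identical and 66.7% differed, so most differences were from an entry of another species. Without species, arm and variant, the names comprised 430 miRNAs, and both arms were listed for 171 of them.

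All 8 members of the striated muscle list were in the catalogue, under 17 names. They were miR-1, miR-133a, miR-133b, miR-206, miR-208a, miR-208b, miR-486 and miR-499. All 6 annotated goat genes of this list had a listed product, but so did 231 of 258 (89.5%) of the other annotated miRNA genes. MiR-1 and miR-133a are transcribed together and are abundant in striated muscle, miR-206 and miR-133b form the second such pair and are largely restricted to skeletal muscle, and miR-208b and miR-499 are encoded within myosin heavy chain genes of slow and cardiac muscle. MiR-133a was listed with both arms identical with the goat entry. MiR-1 was listed with the goat sequence, a cattle entry longer by 3 bases at the 3′ end and a new 5′ arm. Goat miR-206 was shorter by 1 base at the 3′ end. Of the list on myogenic differentiation, which includes miR-24, miR-26a, miR-27b, miR-29 and miR-181 members, 14 of 15 members were listed; the exception was miR-322, the rodent name of miR-424, which was listed.

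Families tied to growth and developmental timing were also covered, as were 89.8% of all annotated goat miRNA genes. All 9 members of the let-7 family, whose mature forms accumulate during development, were listed with both arms. All 14 members of the list on the miR-17~92 cluster and its paralogs, known for their role in cell proliferation, were listed. They comprise the related miR-92b, which lies outside these clusters, and the clusters' own members, including miR-17, miR-18a, miR-19b, miR-20a and miR-92a. All 6 miR-30 members, all 4 miR-181 members and all 5 members of the miR-10/miR-196 list of HOX cluster miRNAs were listed. For the family of miR-15, miR-16, miR-195, miR-497 and miR-424, 9 of 10 spellings were present, and for miR-29, 3 of 4. None of the 8 pluripotency miRNAs (miR-302a to miR-302d, miR-367, miR-371 to miR-373) was among the listed names, but none of them is an annotated goat miRNA gene in assembly ARS1.2 either, so this says little about the muscle.

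The imprinted DLK1-DIO3 locus, whose homologue in sheep carries the callipyge muscle hypertrophy mutation, supplied more names than any other of the 16 lists. Its list was also the longest, with 61 spellings against 15 for the next longest, so this rank can come from list length. The 54 of its 61 spellings that were listed accounted for 118 distinct names, of which 43 were identical with the registry. They included miR-127, miR-136, miR-379, miR-381, miR-409, miR-410, miR-411a, miR-432, miR-433, miR-493, miR-495 and 5 members of the miR-376 group. All 44 annotated goat genes of this list had a listed product, against 193 of 220 (87.7%) of the other annotated miRNA genes (two-sided Fisher's exact p = 0.0113, adjusted p = 0.169 over 15 lists). The difference therefore did not pass after adjustment. For the epithelial list, 3 of 5 annotated genes had a listed product (two-sided Fisher's exact p = 0.0831, adjusted p = 0.623), and the other 13 lists tested had an adjusted p of 1. The longest of these 13, with 14 of 14 annotated genes listed, gave p = 0.374 before adjustment (two-sided Fisher's exact test). Lists this short therefore could not pass through full coverage, and the test says nothing about higher coverage in them.

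**Figure D2:**
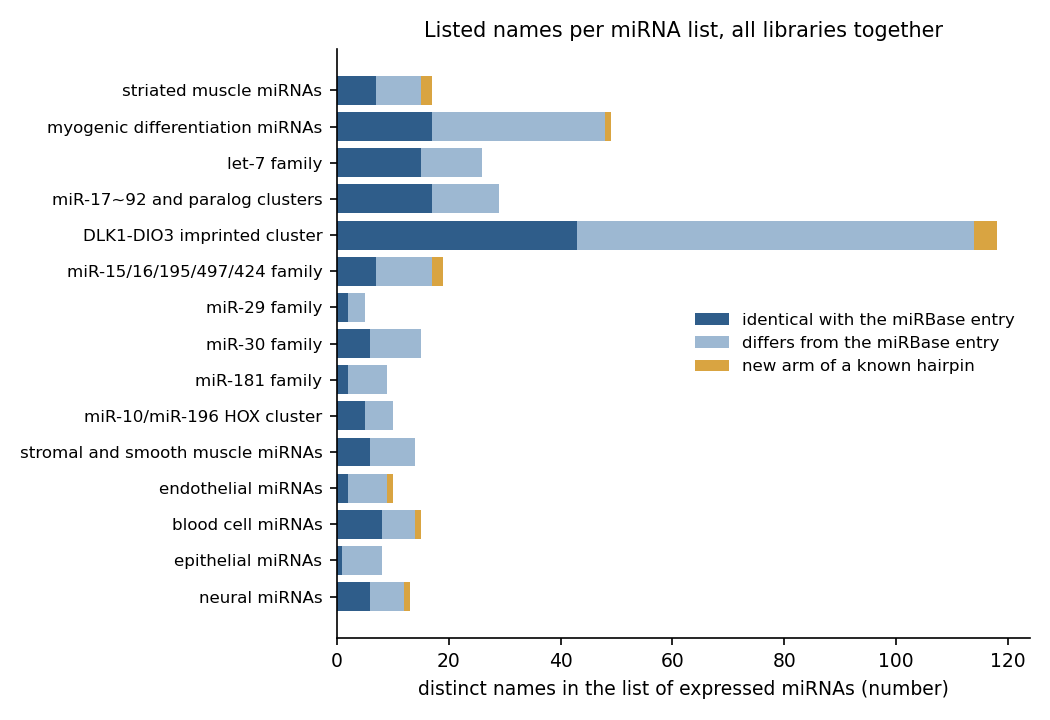
Number of distinct names (horizontal axis) belonging to each miRNA list (vertical axis) for all 6 libraries together, split by whether the sequence equals the miRBase entry, differs from it or is a new arm of a known hairpin. The DLK1-DIO3 list, with 61 spellings, holds 118 names and the striated muscle list, with 8, holds 17.

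Markers of other cells that a piece of muscle can hold were present as well. Full coverage is not particular to them, since 89.8% of all annotated goat miRNA genes had a listed product. All 9 blood cell miRNAs were listed, among them miR-451 and miR-144 of red blood cells, miR-223 of myeloid cells, and miR-142, miR-150 and miR-155 of white blood cells. All 5 endothelial miRNAs were listed, including miR-126. Of the stromal and smooth muscle list, 6 of 7 were listed, including miR-143, miR-145, miR-199a and miR-214. The name miR-199b was not listed, which by name alone does not show that this miRNA was absent. Of the epithelial list, 6 of 10 spellings were present, including miR-200b, miR-205 and miR-375, whereas miR-141 and miR-429 were not among the listed names. Of the neural list, 6 of 8 spellings were present, including miR-9, miR-124a and miR-138, whereas miR-137 was not among them. Presence in the catalogue says that a sequence was listed for at least 1 of the 6 libraries, not at which level.

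Of the 264 miRNA genes in the RefSeq annotation of assembly ARS1.2, 237 (89.8%, 95% exact interval 85.5 to 93.2%) matched a listed name. Counting only names with a sequence identical with the registry, 173 genes (65.5%) matched. The 27 genes without a match included MIR449A, MIR449B and MIR449C, known from ciliated epithelia, MIR137 and MIR153, known from neurons, MIR202, known from gonads, and MIR184. MIR147, MIR199B and MIR545 had no match either. These are examples, and whether missing genes go with a tissue was not tested. Of the annotated genes of the neural list, 5 of 6 had a listed product, and of the epithelial list 3 of 5. The genes without a match also included MIR2284A to MIR2284E, which belong to a large ruminant family of near-identical copies whose names cannot be assigned with certainty.

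Where a listed sequence differed from the registry, the 3′ end was the more variable. Of the 534 differing names, 232 changed only at the 3′ end, 53 only at the 5′ end, 65 at both ends, and 184 carried a substitution. For 387 of the 534, the entry was that of another species, so the change is not one from a goat entry. Among names without a substitution, the 3′ end was longer than in the registry in 213 and shorter in 84 (exact binomial p = 4.4e-14). At the 5′ end 73 were longer and 45 shorter (exact binomial p = 0.0126). Names are not independent of each other, so these p-values describe the catalogue. Among goat entries, 61.4% of 158 sequences from the 5′ arm and 56.3% of 158 from the 3′ arm were identical with the registry, a difference that did not pass the test (two-sided Fisher's exact p = 0.424).

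The listed sequences were 18 to 26 nt long, with a mode at 22 nt. This length held 426 of 1208 sequences (35.3%, 95% exact interval 32.6 to 38.0%), followed by 23 nt with 224 (18.5%) and 21 nt with 184 (15.2%). Together, lengths of 21 to 23 nt made up 69.0%, those of 18 to 20 nt 22.4%, and those of 24 to 26 nt 8.61%. The total of 1208 equals the rows of the name list, in which 86 names occur more than once, rather than its 1120 distinct names. The lengths are given for all libraries together, so no comparison of stages was possible.

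**Figure D3:**
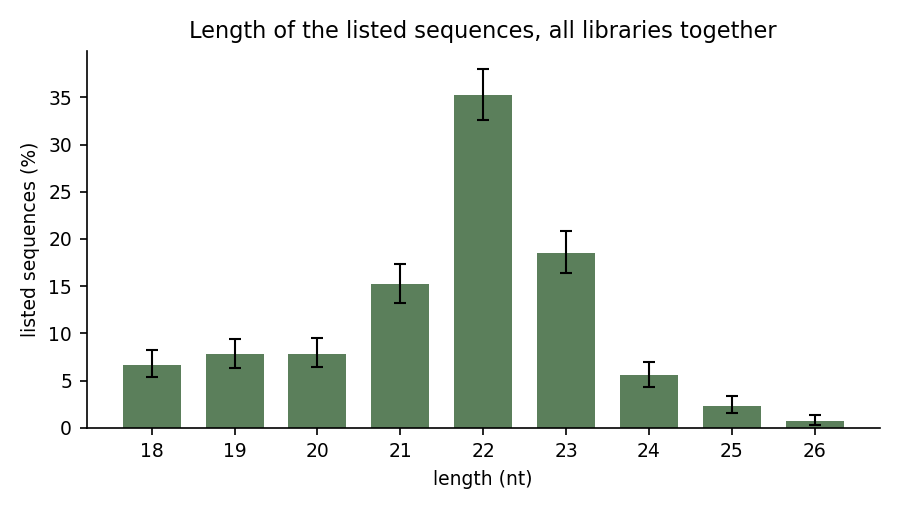
Percent of the 1208 listed sequences (vertical axis) at each length in nucleotides (horizontal axis), all 6 libraries together. Error bars are exact 95% intervals for counting error; 22 nt is the most frequent length with 35.3%.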

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

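Of 36 alternatives, 30 with a test kept the direction and side of the threshold and 2 shares without a test stayed within their intervals. For 3 against 3 libraries this says little, since the exact permutation test used there cannot pass 0.05. The difference in distinct miRNAs, -107 with all classes, was -70.0 without predicted ones, -104 without classes gp2b and gp3, -34.3 in class gp1a alone and -75.7 for hairpins. Leaving out 1 library at a time gave differences from -128 to -82.5 miRNAs (exact permutation p from 0.10 to 0.20), and from -3.35 to -2.92 percentage points for the share of predicted miRNAs. With same-numbered libraries as pairs (a replicate block), the mean difference stayed at -106.667 with an exact sign-flip p = 0.25, the smallest that 3 pairs allow, and the share of predicted miRNAs differed by -3.08 points, also with p = 0.25. Deviations of same-numbered libraries from their stage means had correlations over 6 classes of 0.0122, 0.735 and 0.275. These were not tested and rest on few classes, so they cannot decide whether the numbers pair the samples, which the labels do not say. The share of annotated goat miRNA genes with a listed product was 65.5% with identical sequences only, and the share of names identical with the registry was 30.8% without predicted miRNAs, because fewer names were counted in each case. The full coverage of the run of neighbouring genes from MIR493 to MIR656 exceeded that of other genes by 12.3 percentage points. It was 15.1 points with goat-prefixed names only and 6.73 points with identical sequences only (two-sided Fisher's exact p = 0.0022 and 0.491, against 0.00655 with all names). The number of families with G9T was 8 without names that also change the 5′ end (permutation p = 0.0452, against 0.0529 with all), 7 without new arms (permutation p = 0.0547), and 7 without the miR-6236 and miR-6240 families (permutation p = 0.334), which both carry G9T, so that leaving them out lowers the number by construction. The cause of these last differences was not tested. All these alternatives except the exclusion of predicted miRNAs and leaving out libraries for the number of miRNAs were chosen after seeing the data. The planned minimum of 3 or 10 reads, and every alternative for differing miRNAs, lists and the most abundant miRNAs, were not run, since they need a level per library. Unknown depth limits all comparisons of what was detected.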

Other observations

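All tests in this part were chosen after the values were seen. Some families supplied far more names than others. The miR-378 family, whose main member is encoded within a gene for a regulator of mitochondrial metabolism and is abundant in muscle, had 41 distinct names, of which 2 carried the goat prefix and 25 a substitution. The ruminant miR-2285 and miR-2284 families had 32 and 12 names, none of them with the goat prefix, while none of the 5 annotated goat MIR2284 genes matched by name. The miR-339 family had 28 names, miR-1260 had 27, miR-6236 had 25 and miR-6240 had 19, again none with the goat prefix. Of these, 15, 11, 13 and 14 carried a substitution. Let-7 had 26 names, 16 of them with the goat prefix and 5 with a substitution.

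The 45 annotated miRNA genes that follow each other from MIR493 to MIR656 within the DLK1-DIO3 locus all had a listed product, against 192 of 219 annotated genes elsewhere. With identical sequences only, 32 of the 45 and 141 of the 219 had one (two-sided Fisher's exact p = 0.491). The run was delimited after the annotation had been compared with the names and holds the 44 annotated genes of the DLK1-DIO3 list plus MIR3955, so it is no evidence apart from that list, whose test did not pass after adjustment.

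A single substitution was carried by 260 names, 179 of them differing from a registry entry and 81 new arms, for which what the substitution is relative to is not known here. Many of these names carried the prefix of another species, so a substitution need not be a difference from a goat entry. Among these 260, changes to T made up 36 of 54 (66.7%) at position 21 or beyond and 69 of 206 (33.5%) before it (two-sided Fisher's exact p = 1.81e-05). With each combination of family, substitution and position counted once, they made up 28 of 46 (60.9%) and 43 of 158 (27.2%) (two-sided Fisher's exact p = 4.29e-05). Without new arms they made up 28 of 43 (65.1%) and 43 of 136 (31.6%) (two-sided Fisher's exact p = 0.000142). Names and combinations are not independent, so these p-values describe the catalogue. By names, G-to-T changes were the most frequent kind, with 60, ahead of T-to-C with 45. By combinations, T-to-C led with 44 of 204, ahead of G-to-T with 39, because 13 G9T names came from miR-6236 alone and other families also repeat.

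Fewer distinct miRNAs in lambs could come from lower sequencing depth, and read totals, which would show the depth, are not used here. Class gp2b, detected less completely in fetuses (78.9% of the class per library) than class gp1a (93.3%), would lose at least as large a share if completeness tracks abundance, but what gp2b holds is not known here. The ratio of gp2b to gp1a was 0.471 ± 0.00777 (SD, n = 3) in fetuses and 0.512 ± 0.0184 (SD, n = 3) in lambs, higher by 0.0411 without overlap (exact permutation p = 0.10, the smallest possible), but counted as hairpins it overlapped between stages (exact permutation p = 0.30), so depth as the whole cause is not excluded. Completeness in fetuses fell from gp1a (93.3%) over gp1b (79.5%) and gp2a (73.5%) to gp4 (60.5%). The lamb to fetus ratios of these classes fell in the same order, 0.910, 0.857, 0.791 and 0.639, as lower depth would give. Classes gp2b (78.9%, ratio 0.989) and gp3 (74.0%, ratio 0.982) departed from this order. The gaps between these ratios were not tested, and the numbers of gp2a, gp2b and gp3 overlapped between stages. Depth and stage therefore cannot be told apart here, and a developmental difference between mid-gestation and birth stays open and untested.

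The names of the 168 predicted miRNAs end in a pair of numbers. The second never increased as the first rose (Spearman's rho = -0.998 across names), so the first may be a rank and the second a copy number over all libraries. If so, the predicted miRNAs are mostly sequences with few reads over all 6 libraries: the lowest number was 5, the median was 17, and 55 of 168 (32.7%) were under 10. The highest was that of PC-5p-477_14754, with 14754.

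The substitution G9T (positions from the 5′ end as printed in the names) occurred in 24 names, 16 of them new arms, from 9 families: miR-23, miR-100, miR-199, miR-300, miR-320, miR-381, miR-2284, miR-6236 and miR-6240. All of these names carried the prefix of another species, so where a registry entry was compared, it was not a goat entry. A recurrent sequencing error at this position would be a candidate explanation. Shuffling the positions over the 204 combinations of family, substitution and position gave a cell with 9 or more families with a permutation p = 0.0529. It was 0.0452 without names that also change the 5′ end, on the other side of 0.05, and 0.0547 without new arms, so chance stays open. Families were set by the number in the name, so related miRNAs with different numbers were counted as separate families in this test. G22T was equally widespread, also in 9 families. No biological explanation was tested.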
